A study of Mus musculus with 2 samples.

How the data were processed

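H3K27me3, a histone mark written by Polycomb repressive complex 2, was measured by chromatin immunoprecipitation followed by sequencing in the intestine of mouse embryos aged 14.5 days. Per the labels, 2 biological replicates made up 1 group. Replicate 1 was a pool of intestines from 24 embryos and replicate 2 a pool from 34 embryos, both of the strain B6NTac;B6NCrl/Lap and of pooled male and female embryos. The replicates came from separate pools of embryos, so each counted as an independent sample. No second group was measured, and the control library was not analysed here.

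The deposited data used here were 4 peak lists on the mouse build mm10: 1 for each replicate, 1 pooled list and 1 list of replicated peaks. Per the file headers, the replicate 1 and pooled lists were each derived from alignments with 2 further input files, and the replicate 2 list from its alignments with 1 further input file. The replicated list was derived, per the file headers, from the pooled list and the lists of both replicates. The aligner, the peak caller, its thresholds and the overlap rule behind the replicated list are not given in the sources used here. Each deposited peak carries a display score between 10 and 1000, scaled by the authors, which was not used. Each peak also carries the authors' enrichment over background, a ratio called fold here, as their peak caller gave it. The deposited lists further give −log10 of a p-value and −log10 of a q-value per peak, as the authors' caller reported them. These values are the authors' own and were used to describe, rank or filter peaks. The fold was also ranked across the peaks shared by the replicates and compared between sets of genes within each replicate. Read counts were not in the lists, so the sequencing depth is unknown. Intervals printed for shares are Wilson 95% intervals and cover counting error over peaks or genes, not the difference between embryos.

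Peaks were placed on the GRCm38.p6 assembly, the same build as mm10, with the GENCODE M21 annotation. The gene set was the 21755 protein-coding genes on the 19 autosomes and chromosome X. The transcription start site (TSS) was the annotated 5′ end of the gene. A gene was called marked when at least 1 bp of its promoter, the TSS ± 1 kb, lay under a replicated peak. The cover of a gene was the percentage of the TSS ± 2.5 kb under peaks. It was computed for the replicated list and for each replicate alone, the latter given as mean ± SD over the 2 replicates. Domains were made by joining replicated peaks within 3 kb of each other. The CpG ratio of a promoter was the observed over the expected number of CpG dinucleotides in the reference sequence, and a ratio of at least 0.6 was called CpG-rich. Coordinates are 1-based.

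Overlap between the replicates was set against 100 random placements of the peaks on their own chromosomes, avoiding assembly gaps. The genomic distribution of replicated peaks was set against placements made the same way, with promoters counted first, then exons, introns and intergenic sequence. Gene lists were tested with two-sided Fisher exact tests of marked members against all other protein-coding genes, with Benjamini-Hochberg adjustment over 17 lists. A further test set each list against 10000 random lists with the same promoter CpG deciles. Differences in cover between sets of genes were tested with two-sided permutation tests of 100000 resamples, for which 1e-05 is the smallest p they can give. For the random lists the smallest two-sided p is 0.0002. Genes and peaks are not independent replicates, and neighbouring genes can share a domain, so these tests describe this tissue and not the variation between embryos. With 1 group, no test between groups of samples was possible.

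The lists held Hox genes, intestinal epithelial regulators, intestinal epithelial effector genes, secretory and enteroendocrine regulators, gut mesenchyme and smooth muscle genes, enteric neural crest genes, and endothelial and blood genes. Further lists held regulators of foregut organs, of the central nervous system and senses, of heart, skeletal muscle and limb, and of the urogenital tract. The remaining lists held secreted developmental ligands, cyclin-dependent kinase inhibitors, germline genes, differentiated-cell genes of other organs, housekeeping genes and olfactory receptors. The olfactory receptors were taken by their symbols. The other lists named 392 genes, all of which were found in the annotation. The lists, the tests and the alternatives were chosen before the data were examined, except for those said to have been chosen later.

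The genes named in the text followed a rule also chosen before the data were examined. Per list these were the 4 marked members with the most cover (ties broken by mean fold, then symbol) and the first 2 unmarked members in symbol order. Lists with fewer marked than unmarked members could have up to 6 marked and 4 unmarked genes named. Every Hox gene, every gene of the contrast between regulators, and the protein-coding genes with a TSS in the 15 longest domains could be named as well. Any other gene is said to have been chosen after its values were seen.

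The alternatives were the pooled peaks, replicated peaks with a fold at or above the median of the list, replicated peaks with a −log10 q of at least 5, each replicate alone, and base pairs covered by both replicates. Others changed the promoter to ± 500 bp or ± 2.5 kb, asked for at least 500 bp of it, or took any TSS of the gene. Further ones kept 1 gene per 100 kb, matched genes on promoter CpG, joined domains within 1 or 10 kb, changed the overlap that counted as shared, or left out 1 Hox cluster at a time. Leaving out chromosome X and taking as background only genes outside every other list were added after the data had been seen. So were the contrast among promoters with a CpG ratio under 0.6 and the tests without some Hox genes with a displaced TSS.

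The interval cover, peak overlap, promoter share, list tests, permutation tests and CpG matching were tested on simulated data before they were applied. The joining of domains, the Jaccard index, the rank correlation and the comparisons of chromosome X peaks were not. Covered lengths equalled a direct count in 500 of 500 windows. Copied peaks were found as shared in 100% of 24743 cases, and peaks placed at random in 1.22% of 24785. All 20 simulated lists of marked genes and 0 of 20 lists of other genes were called by the Fisher tests. Permutation tests fell under 0.05 for 10 of 200 unchanged sets and for 49 of 50 shifted sets. These simulated sets had equal spread, unlike the covers compared between sets of genes below. Tests against CpG-matched lists fell under 0.05 for 4 of 100 lists marked by CpG alone, and for 98 of 100 such lists with 10 more members marked. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.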

Results

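H3K27me3, a mark of genes silenced by Polycomb proteins, was mapped in the intestine of mouse embryos at 14.5 days of gestation. The design held 1 group with 2 biological replicates, a pool from 24 embryos (replicate 1) and a pool from 34 embryos (replicate 2). The replicate 1 list held 49528 peaks that covered 27.7 Mb, with a median length of 285 bp. The replicate 2 list held 31120 peaks that covered 16.8 Mb, with a median length of 298 bp. Statements on genes rest on 19783 replicated peaks, which covered 22.2 Mb, or 0.844% of the genome, with a median length of 534 bp. Their fold, as the authors gave it, ran from 1.56 to 13.5 with a median of 3.57. The depth is unknown, so a gene without a peak is one where none was called, not one shown to lack the mark.

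The first comparison asked how far the replicates shared the mark. In gene lists chosen before the data were examined, each replicate alone marked the promoters of all 60 regulators of the central nervous system and senses. Of the 39 Hox genes, which set position along the body axis, replicate 1 marked 35 and replicate 2 marked 33. Of 23 regulators of the intestinal epithelium they marked 14 and 13. Over all protein-coding genes replicate 1 marked 3889 and replicate 2 marked 3100, of which 2878 were marked in both.

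Across all peaks, 15929 of the 49528 in replicate 1 (32.2%, Wilson 95% interval 31.8 to 32.6%) overlapped a replicate 2 peak by at least 1 bp. In the other direction, 21697 of the 31120 in replicate 2 (69.7%, interval 69.2 to 70.2%) overlapped a replicate 1 peak. Over 100 random placements the highest values were 1.58% and 2.17%. Among peaks with a −log10 q of at least 5, 86.2% of the 7982 in replicate 1 and 99.8% of the 4396 in replicate 2 overlapped a peak of the other replicate. The Jaccard index over base pairs was 0.416, and the highest over random placements was 0.00501. The authors' fold had a Spearman rho of 0.480 across the 15929 shared peaks, which are not independent replicates. All 19783 replicated peaks had the coordinates of a pooled peak. Of them 65.2% overlapped both replicates, 32.1% exactly 1 and 542 peaks neither. Asking for an overlap over 50% of both peaks lowered the first share to 13.6%.

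Chromosome X separated the replicates. It held 9558 replicate 1 peaks (19.3%, interval 18.95 to 19.65%) and 2933 replicate 2 peaks (9.42%, interval 9.11 to 9.75%), a ratio of 3.26. On the 19 autosomes this ratio ran from 1.29 to 1.70, with a median of 1.42. In the replicated list 133 of 948 genes on X (14.03%) were marked, against 14.7% of autosomal genes (two-sided Fisher exact p = 0.606). Replicate 1 alone marked 230 genes on X and replicate 2 alone 142. The difference in X share rests on 1 library per side and has no replicate of its own.

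**Figure D1:**
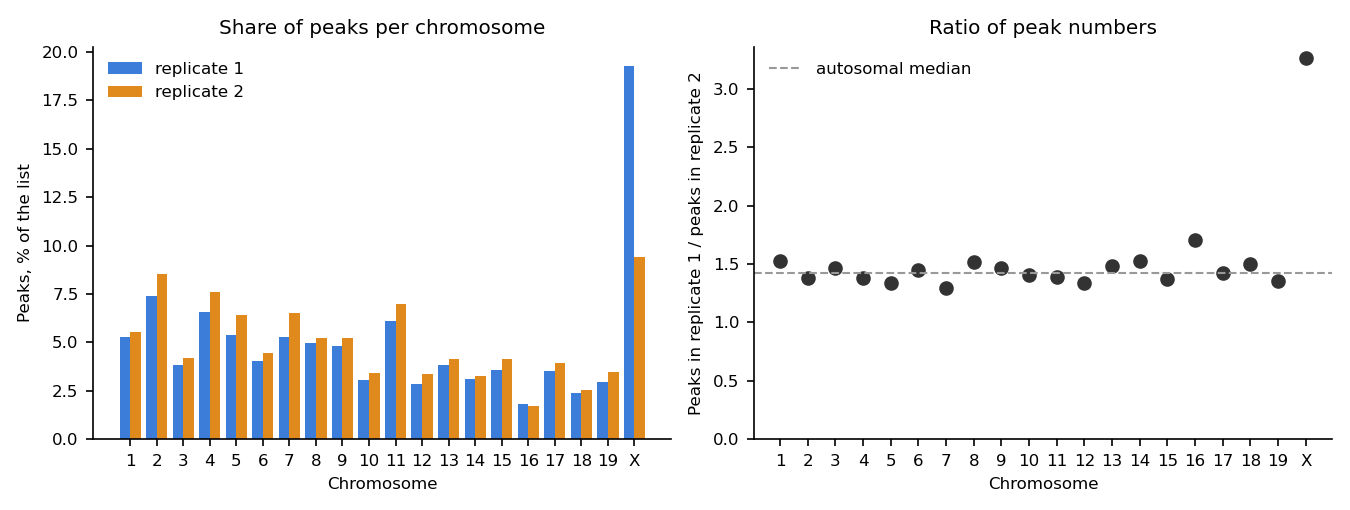
Left, the percentage of each replicate's peaks on each chromosome (blue, replicate 1; orange, replicate 2); right, the number of replicate 1 peaks over the number of replicate 2 peaks per chromosome, with the autosomal median of 1.42 as a dashed line. Chromosome X lies at 3.26 and the autosomes between 1.29 and 1.70; each point is a single ratio without an error bar.

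The next question was where the replicated peaks lay. Promoters of protein-coding genes held 17.3% of the marked sequence, 10.2-fold more than the 1.69% ± 0.109 (SD) over 100 random placements. Exons outside promoters held 10.1%, a 2.89-fold excess over 3.51% ± 0.143. Introns held 34.0% against 36.9% ± 0.564, and intergenic sequence 38.6% against 57.9% ± 0.593. Promoters took 14.2% of the sequence under replicate 1 peaks and 17.1% under replicate 2 peaks. In all, 3190 of 21755 protein-coding genes (14.7%) were marked, where random placements marked a mean of 538 and at most 590. Of these genes 2793 (87.6%) were also marked in each replicate alone. Promoters with a CpG ratio of at least 0.6 were marked in 18.2% of cases and the others in 12.8%. Over the TSS ± 2.5 kb of marked genes, the median cover was 50.6%.

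Regulators listed under organs other than the intestine were marked in 102 of 111 cases, with a lower share for heart, muscle and limb than for the others. All 60 regulators of the central nervous system and senses were marked (Wilson 95% interval 94.0 to 100%), in each replicate alone too. They included Olig1, which specifies oligodendrocytes and motor neuron progenitors, and Pax7, which acts in the dorsal neural tube and muscle stem cells. Lhx1 and Evx2, homeobox genes of spinal interneurons and of limb and nervous system, were among them. The cover of all 4 was 100% by replicated peaks, and over the replicates it was 100% ± 0 for Olig1, 98.5% ± 2.06 for Pax7, 98.5% ± 2.11 for Lhx1 and 97.2% ± 3.99 for Evx2 (SD, n = 2). The list was marked 6.93-fold more often than other genes (two-sided Fisher exact p = 5.84e-51, adjusted p = 4.97e-50).

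Among foregut regulators, 15 of 17 (88.2%) were marked, with 15 in each replicate. Pdx1, which directs the pancreas and duodenum, had a cover of 96.7% ± 4.69, and Nkx2-1, the regulator of lung and thyroid, 98.8% ± 0.255 (SD, n = 2). Sox2, which specifies oesophagus and stomach, reached 93.7% ± 3.82, and Foxe1, a thyroid gene, 94.4% ± 1.98. Foxn1, the thymus regulator, and Trp63, the regulator of stratified epithelia, had no replicated peak at the promoter. The excess was 6.04-fold (Fisher exact p = 3.07e-11, adjusted p = 1.04e-10).

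Heart, skeletal muscle and limb regulators were marked in 18 of 24 cases, 19 in replicate 1 and 18 in replicate 2 (5.14-fold, Fisher exact p = 5.2e-11, adjusted p = 1.47e-10). The cover was 97.2% ± 3.97 at the heart gene Tbx20, 98.3% ± 2.46 at the hindlimb gene Pitx1 and 96.6% ± 1.74 at Myod1, the master regulator of skeletal muscle (SD, n = 2). Its relatives Myf5, Myf6 and Myog were unmarked, as were the paraxial mesoderm genes Tbx6 and Msgn1 and the limb gene Prrx2. Urogenital regulators were marked in 9 of 10 cases, 10 in replicate 1 and 9 in replicate 2 (6.15-fold, Fisher exact p = 2.7e-07, adjusted p = 5.73e-07). Pax2 and Six2, both needed for the kidney, had covers of 97.4% ± 3.75 and 92.9% ± 6.52, and Eya1 was unmarked at its annotated 5′ end. With any TSS of the gene, and with the pooled peaks, all 10 were marked.

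**Figure D2:**
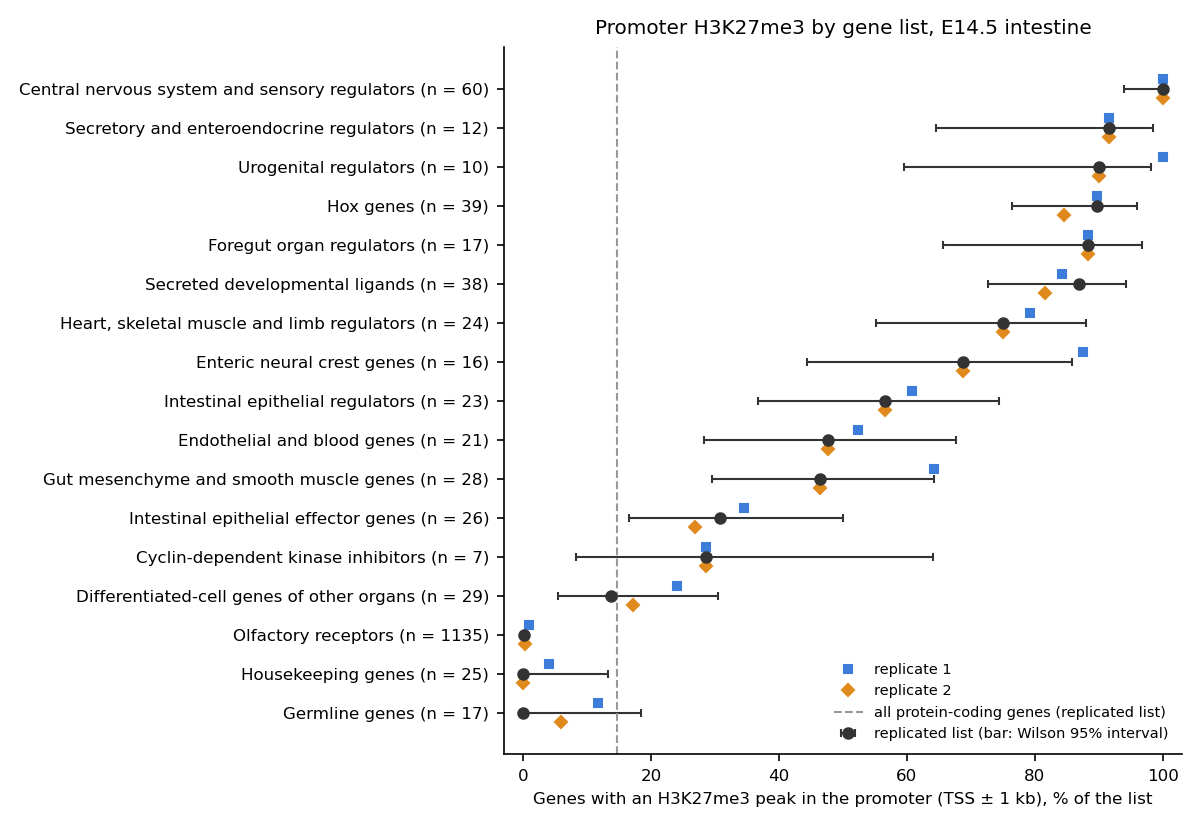
Percentage of each gene list with an H3K27me3 peak at the promoter (TSS ± 1 kb); black circles, replicated list with Wilson 95% intervals; blue squares, replicate 1; orange diamonds, replicate 2; dashed line, 14.7% of all protein-coding genes. Central nervous system regulators lie at 100%, intestinal epithelial regulators at 56.5% and housekeeping and germline genes at 0%.

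Genes of the intestine itself were split. The intestine was profiled as a mixed tissue, so no peak here or below can be assigned to the epithelium or to another cell type. Of 23 intestinal epithelial regulators, 13 (56.5%, interval 36.8 to 74.4%) were marked, 14 in replicate 1 and 13 in replicate 2. Cdx2, which gives the epithelium its intestinal identity, had a cover of 89.6% ± 14.7, and its relative Cdx1 71.2% ± 7.59 (SD, n = 2). The endoderm factors Foxa1, Foxa2 and Gata4 had covers of 85.2% ± 17.1, 90.6% ± 6.49 and 79.8% ± 5.59. Lower values were found at Sox9, a factor of crypt progenitors (29.0% ± 18.4), Klf5, a factor of proliferating epithelium (34.9% ± 26.4), and Klf4, a goblet cell factor (14.7% ± 3.69). Hnf4a, Hnf4g and Hnf1a, activators of absorptive cell genes, had no base under a peak in either replicate, and Isx and Tcf7l2, the Wnt pathway effector, were also unmarked. The list was marked 3.87-fold more often than other genes (Fisher exact p = 3.8e-06, adjusted p = 6.46e-06).

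Effector genes of the epithelium were marked in 8 of 26 cases (30.8%), 9 in replicate 1 and 7 in replicate 2. The marked ones included genes of cell junctions: Cdh1, which encodes E-cadherin, had a cover of 77.6% ± 12.8, Cldn7 81.9% ± 6.76, Cldn3 73.6% ± 15.5 and Epcam 52.9% ± 8.85 (SD, n = 2). The marked transporter genes Slc5a1 and Slc15a1 had covers of 31.8% ± 15.7 and 22.4% ± 5.05. The enterocyte genes Alpi, Anpep, Apoa1 and Apoa4 had no base under a peak in either replicate. The 2.10-fold excess did not pass the adjusted threshold (Fisher exact p = 0.0445, adjusted p = 0.054). It stayed short in 6 of 14 alternatives and passed in the others, with adjusted p-values from 0.00811 to 0.14.

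Regulators of rare or later intestinal cells were marked almost throughout. Of 12 secretory and enteroendocrine regulators, 11 were marked in the replicated list and in each replicate (6.27-fold, Fisher exact p = 6.9e-09, adjusted p = 1.68e-08). Neurog3, which starts enteroendocrine differentiation, had a cover of 99.3% ± 0.99, Insm1 98.2% ± 2.49, Pax6 98.7% ± 1.85 and Gfi1 98.6% ± 2.01 (SD, n = 2). Spdef, which acts in goblet and Paneth cell maturation, was unmarked.

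Among enteric neural crest genes 11 of 16 were marked, 14 in replicate 1 and 11 in replicate 2 (4.70-fold, Fisher exact p = 1.41e-06, adjusted p = 2.67e-06). Phox2b and Ascl1, factors of autonomic neuron progenitors, had covers of 93.6% ± 4.10 and 97.1% ± 4.11, and Tubb3, a tubulin of neurons, 96.6% ± 1.71 (SD, n = 2). The endothelin receptor gene Ednrb and the neuronal gene Elavl4 were unmarked, although Ednrb had a cover of 16.7% in replicate 1 alone.

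Gut mesenchyme and smooth muscle genes were marked in 13 of 28 cases, 18 in replicate 1 and 13 in replicate 2 (3.18-fold, Fisher exact p = 6.04e-05, adjusted p = 9.34e-05). Among its transcription factors the cover was 80.5% ± 6.62 at Foxl1, 75.6% ± 18.2 at Foxf2, 80.5% ± 0.212 at Nkx3-2 and 42.3% ± 1.30 at Nkx2-3 (SD, n = 2). The contractile gene Acta2, the muscle filament gene Des and the collagen genes Col1a1 and Col3a1 were unmarked. Endothelial and blood genes were marked in 10 of 21 cases, 11 in replicate 1 and 10 in replicate 2 (3.25-fold, Fisher exact p = 0.000337, adjusted p = 0.000478). The haematopoietic factor Tal1 had a cover of 93.1% ± 3.38, Sox17, a factor of arterial endothelium, 95.8% ± 3.49, and Kdr, the endothelial VEGF receptor, 78.4% ± 0.424. The endothelial genes Cdh5 and Emcn and the erythroid genes Gata1 and Klf1 were unmarked. Cdh5 and Klf1 had covers of 5.44% and 4.20% in replicate 1 alone, and Emcn and Gata1 had none in either replicate.

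Secreted developmental ligands were marked in 33 of 38 cases, 32 in replicate 1 and 31 in replicate 2 (5.97-fold, Fisher exact p = 6.23e-23, adjusted p = 2.65e-22). Wnt3 had a cover of 100% ± 0, Wnt7a 98.7% ± 1.89 and Fgf8 96.2% ± 5.40 (SD, n = 2), whereas Fgf10 and Bmp5, signals of mesenchyme, had none at the annotated 5′ end. With any TSS of the gene 37 of 38 ligands were marked, so Fgf10, Bmp5 or both had a peak at another TSS. Of 7 cyclin-dependent kinase inhibitor genes, 2 were marked in the replicated list and in each replicate (Fisher exact p = 0.274, adjusted p = 0.291). These were Cdkn2a and Cdkn2b, neighbouring senescence genes on chromosome 4, with covers of 100% ± 0 and 87.2% ± 10.7. Cdkn1a, Cdkn1b, Cdkn1c and Cdkn2c had no replicated peak within 1 kb of the TSS. With the wider promoter of ± 2.5 kb this list passed the threshold (Fisher exact test, adjusted p = 0.0225), as it did with any TSS (adjusted p = 0.0207).

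The remaining lists held few marked genes. Olfactory receptor genes, the chemosensory receptors of the nose, were marked in 1 of 1135 cases, 10 in replicate 1 and 3 in replicate 2, against 15.5% of other genes (Fisher exact p = 1.45e-78, adjusted p = 2.46e-77). Lists matched on promoter CpG had a mean of 22.8 marked genes, so the fold was 0.0438 there (adjusted p = 0.00034 from random lists, not an exact test). The marked one was Olfr95, with a cover of 31.6% ± 3.69 (SD, n = 2). Housekeeping genes such as Actb, B2m and Eef1a1 were marked in 0 of 25 cases (interval up to 13.3%), 1 in replicate 1 and 0 in replicate 2 (Fisher exact p = 0.0413, adjusted p = 0.054). Germline genes such as Dazl, Ddx4 and Asz1 were marked in 0 of 17 (interval up to 18.4%), 2 in replicate 1 and 1 in replicate 2 (Fisher exact p = 0.159, adjusted p = 0.18). Against lists of the same promoter CpG content the housekeeping and germline lists passed the threshold, with adjusted p-values of 0.00971 and 0.034. Differentiated-cell genes of other organs were marked in 4 of 29 cases, 7 in replicate 1 and 5 in replicate 2 (0.941-fold, Fisher exact p = 1, adjusted p = 1). These were the muscle genes Acta1 (80.6% ± 9.90) and Ckm (67.6% ± 1.99), the neuronal gene Syt1 (62.4% ± 15.4) and the myelin gene Mbp (32.1% ± 23.5). The liver gene Alb and the stomach proton pump genes Atp4a and Atp4b had no base under a peak.

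Of the 17 lists, 11 were marked more often than other genes, 1 less often and 5 passed neither way. Against lists matched on promoter CpG, 12 were marked more often. There the 35 marked Hox genes stood against a mean of 7.82 and a highest of 18, and the 60 nervous system regulators against a mean of 11.0 and a highest of 25.

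The design also set the regulators of other organs against those of the intestinal epithelium. Of 111 regulators of foregut organs, nervous system, heart, muscle, limb and urogenital tract, 102 were marked (91.9%, interval 85.3 to 95.7%). Of the 23 epithelial regulators 13 were (56.5%), a difference of 35.4 percentage points (two-sided Fisher exact p = 0.000115). Hnf4a, Hnf1a and Isx stood on the unmarked side, Pdx1, Sox2 and Myod1 on the marked side. Pdx1 was counted with the foregut organs, although it also directs the duodenum, a part of the intestine. Replicate 1 alone gave 93.7% against 60.9%, and replicate 2 alone 91.9% against 56.5%. Among genes with CpG-rich promoters the difference was not detectable: 64 of 65 regulators of other organs and 11 of 12 epithelial regulators were marked (98.5% and 91.7%, Fisher exact p = 0.289). Among the other promoters, a test added after the data had been seen, 38 of 46 and 2 of 11 were marked, 64.4 percentage points apart (82.6% and 18.2%, Fisher exact p = 0.000107). The CpG ratio still varies among promoters under 0.6, and the sets were not matched on it there, so CpG content may still contribute to that difference. Whether the difference itself changes with CpG content was not tested.

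Along the Hox clusters, posterior genes carried more of the mark than anterior ones. Hox genes of paralog groups 9 to 13, which pattern the posterior body, had a cover of 99.7% ± 0.614 (SD over 16 genes). Those of groups 1 to 8, which pattern more anterior levels, had 58.0% ± 37.5 (23 genes), a difference of 41.7 percentage points (two-sided permutation p = 0.00012). In all 35 of 39 Hox genes were marked, 35 in replicate 1 and 33 in replicate 2 (6.18-fold, Fisher exact p = 2.51e-25, adjusted p = 1.42e-24). The unmarked ones were Hoxa2, Hoxa4, Hoxb3 and Hoxb4, whose mean replicate covers lay between 0% at Hoxb3 and 8.56% ± 12.1 at Hoxa2 (SD, n = 2).

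Differences between the clusters were not tested. In Hoxb (chromosome 11, 96194316 to 96368256) groups 1 to 8 had a cover of 32.6% ± 28.5 over 8 genes, and Hoxb9 and Hoxb13 had 100%. In Hoxa (chromosome 6, 52155590 to 52260880) groups 1 to 8 had 48.4% ± 39.8 over 7 genes and groups 9 to 13 99.2% ± 1.04 over 4. In Hoxc (chromosome 15, 102921103 to 103036852) the values were 97.3% ± 3.16 and 99.8% ± 0.456, and in Hoxd (chromosome 2, 74668310 to 74765142) 86.5% ± 13.3 and 100% ± 0. With each cluster left out in turn, the difference between posterior and anterior groups ran from 28.1 to 49.9 percentage points (permutation p-values up to 0.0011). The annotated TSSs of Hoxa3 (52213336), Hoxc5 (102967443), Hoxd3 (74711927) and Hoxd4 (74711929) lie beside genes of higher paralog number, and the cover was taken there. Those of Hoxd3 and Hoxd4 are 2 bp apart, so nearly the same window was counted for both. In tests added after the data had been seen, the difference was 42.5 percentage points without Hoxd4 (permutation p = 7e-05) and 47.6 without all 4 (permutation p = 2e-05). The test without all 4 kept other genes whose TSS lies just past the end of a gene of higher paralog number. Among them were Hoxc4 (103018934), past Hoxc5 (end 103017429), and Hoxb3 (96323326), past Hoxb4 (end 96321638). Hoxb2 was marked with a cover of 5.62% by a replicated peak, and had no base under a peak of either replicate.

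**Figure D3:**
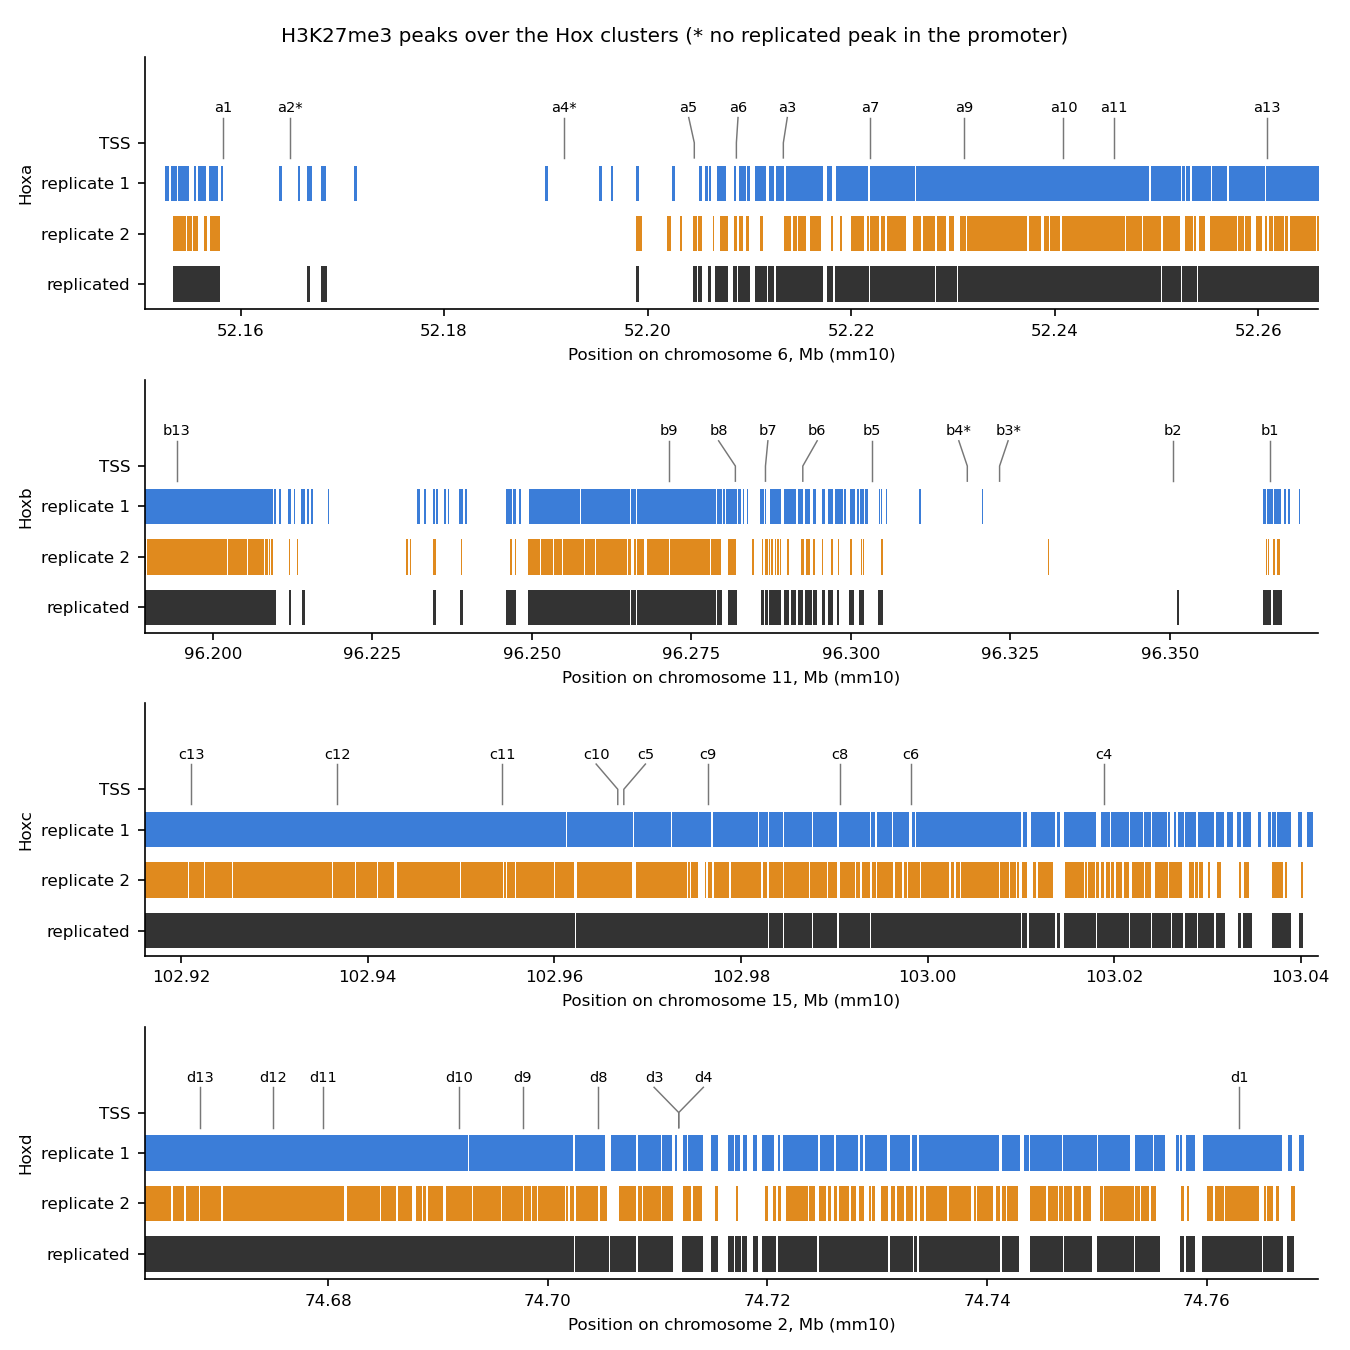
H3K27me3 peaks of replicate 1 (blue), replicate 2 (orange) and the replicated list (black) over the Hoxa, Hoxb, Hoxc and Hoxd clusters, in Mb on mm10, with the TSS of each Hox gene as a line named by cluster letter and paralog number. Asterisks stand at Hoxa2, Hoxa4, Hoxb3 and Hoxb4, which lacked a replicated peak within 1 kb of the TSS.

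The last question was which loci carried the longest stretches of the mark. The replicated peaks formed 8113 domains with a median length of 1.66 kb, of which 590 were at least 10 kb long and held 42.3% of the marked sequence. The longest covered the Hoxc cluster (chromosome 15, 102894107 to 103040275, 146.2 kb) and Hoxd with Evx2 (chromosome 2, 74643387 to 74767941, 124.6 kb). Another (chromosome 7, 79494141 to 79601691, 107.6 kb) held no protein-coding TSS and overlapped Mir9-3, a gene of the neural microRNA miR-9, and its host transcript. Pax3, a regulator of neural crest and muscle progenitors (90.5 kb), and Zic1 with Zic4, zinc finger regulators of the cerebellum (75.2 kb), came next, followed by Hoxa5 to Hoxa13 with the annotated TSS of Hoxa3 (73.8 kb) and Tbx5, a heart and forelimb gene (57.8 kb). Pax2 lay in a domain of 52.5 kb (chromosome 19, 44717162 to 44769698), and beside it stood a domain of 56.8 kb with no protein-coding TSS (44646254 to 44703009). Dmbx1, Nfix, Pax7, Zic2 with Zic5, Hoxb13, and Cdkn2a with Cdkn2b completed the 15, down to 49.8 kb.

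Of the 590 long domains 425 (72.0%) held a protein-coding TSS. Nervous system regulators lay in them in 57 of 60 cases, foregut regulators in 15 of 17 and Hox genes in 32 of 39. Among genes of cells in the gut, secretory and enteroendocrine regulators lay in long domains in 9 of 12 cases, epithelial regulators in 7 of 23, enteric neural crest genes in 5 of 16, mesenchyme and smooth muscle genes in 8 of 28, endothelial and blood genes in 4 of 21 and epithelial effector genes in 0 of 26. Within the 15 longest domains, which were built from peaks of the replicated list, replicate 1 covered between 74.8% and 95.2% of the sequence and replicate 2 between 62.8% and 84.6%. The number of domains depended on the peak list: replicate 1 alone formed 19008, the pooled list 13424, and replicated peaks with a −log10 q of at least 5 formed 4214.

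**Figure D4:**
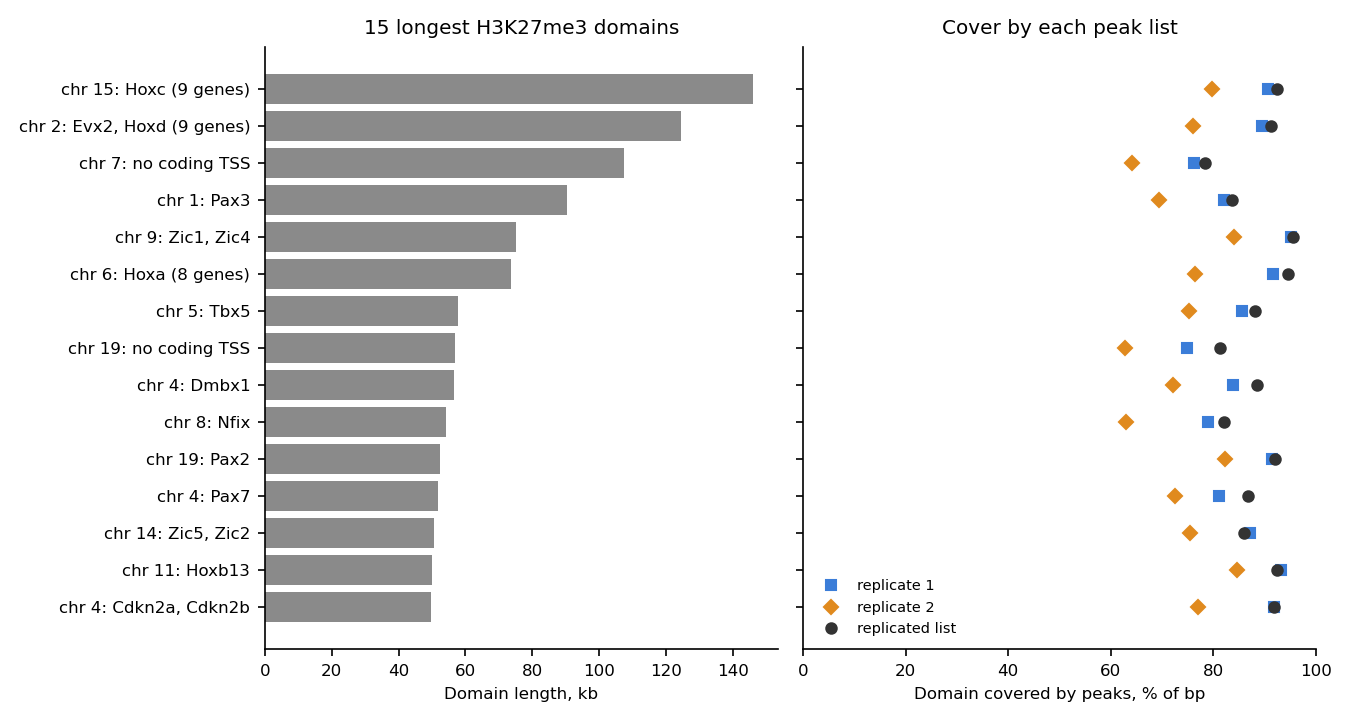
Left, length in kb of the 15 longest domains of replicated peaks joined within 3 kb, named by chromosome and by the protein-coding genes with a TSS inside; right, the percentage of each domain covered by peaks of replicate 1 (blue), replicate 2 (orange) and the replicated list (black). Lengths run from 49.8 to 146.2 kb, and replicate 2 covers less than replicate 1 in all 15.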

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

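The excess of peaks on chromosome X was seen before its tests were chosen. The reading of the window test from its interval was chosen after its value was seen.

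Replicate 1 held 7065 peaks on chromosome X (73.9% of its X peaks) that overlapped neither a replicate 2 peak nor a replicated peak. Gene results from the replicated list did not use them, while the counts given for replicate 1 alone did. On the autosomes this share was 50.8% (20300 peaks), and replicate 2 had 1254 X peaks outside replicate 1 and the replicated list.

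A longer list with weaker peaks may raise the X share, but among the 16756 and 15877 top peaks by the authors' p the X share was still 14.3% against 5.83%, 8.44 percentage points apart. At a −log10 q of at least 5 it was 4.76% against 0.751%. The gap in percentage points was smaller there, where both shares were lower. Relative to replicate 2, the replicate 1 share was larger there than over all peaks, so weaker peaks alone did not make the excess. Base composition may account for part of the excess but not the whole: X peaks in replicate 1 numbered 9558 against 5051 expected at the same GC content, a ratio of 1.89. A few regions alone were argued against by the windows of 5 Mb with at least 20 peaks, of which 20 of 22 (90.9%, Wilson 95% interval from 72.2% upwards) lay above the autosomal ratio. More inactive X chromosomes in the replicate 1 pool, or another X dosage against its control, would both give an excess along X and away from promoters, and cannot be told apart here. A promoter was touched by 4.16% of X peaks against 15.4% of autosomal peaks in replicate 1, but also by 7.57% against 19.5% in replicate 2, and neither the sex ratio of the pools nor the control was analysed here.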

How the results depend on the processing

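Leaving out chromosome X, the background without other lists, the contrast at promoters with a CpG ratio under 0.6, and leaving out Hoxd4 or Hoxa3, Hoxc5, Hoxd3 and Hoxd4 were chosen after the data had been seen. Over all alternatives, 298 values for comparisons kept their direction, their side of the threshold or their size, 14 passed a threshold they had missed, 1 fell short of one, 10 turned direction and 12 moved. For named genes 1094 covers stayed within the spread of the replicates and 436 moved. Unless the construction of the alternative shows it, the cause was not tested.

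The share of replicate 1 peaks that overlapped replicate 2 was 21.7% with 50% of the replicate 1 peak covered, 13.6% with 50% of both peaks, 38.3% with a −log10 q of at least 5 in both lists, 47.0% for the top peaks and 36.7% without chromosome X; in the other direction it was 69.7%. A wider overlap can only lower such a share. The rank correlation of fold was 0.595 with 50% of both peaks and 0.548 with −log10 p in place of fold.

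Epithelial effector genes passed the threshold with pooled peaks (2.00-fold), base pairs in both replicates (2.18-fold), promoters of ± 500 bp (2.20-fold) or ± 2.5 kb (2.049-fold), at least 500 bp covered (2.36-fold), any TSS (2.14-fold) and matched CpG (2.86-fold); replicate 1 alone passed (1.94-fold, adjusted p = 0.0486) and replicate 2 alone did not (1.89-fold, adjusted p = 0.103), both by exact tests. Cyclin-dependent kinase inhibitors did so with ± 2.5 kb (3.38-fold) and any TSS (3.54-fold). Housekeeping genes, at 0, did so in exact tests with ± 2.5 kb (adjusted p = 0.0196) and any TSS (adjusted p = 0.0304). Against random lists of matched CpG, which give no exact test, housekeeping genes (adjusted p = 0.00971) and germline genes (adjusted p = 0.034), both at 0, passed as well.

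Differentiated-cell genes of other organs, at 0.941-fold, turned to an excess that passed no threshold: 1.19-fold with pooled peaks, 1.17-fold with a fold at or above the median, 1.22-fold with a −log10 q of at least 5, 1.11-fold with base pairs in both replicates, 1.13-fold with ± 500 bp, 1.02-fold with ± 2.5 kb, 1.21-fold with at least 500 bp, 1.70-fold with matched CpG, and 1.21-fold to 1.35-fold with each replicate alone. The contrast between regulators fell to 6.79 percentage points (exact p = 0.289) among CpG-rich promoters and was 64.4 (exact p = 0.000107) among the others, and its p ran from 2.32e-05 to 0.00099 in the other alternatives. Merged domains numbered 13424 with pooled peaks, 5040 with a fold at or above the median, 4214 with a −log10 q of at least 5, and 11133 to 19008 with each replicate alone, since these lists hold other numbers of peaks.

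Depth is unknown, so a missing peak sets no upper limit on the mark, and the longer list of replicate 1 was not scaled to replicate 2.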

Other observations

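The gene families by symbol, the strongest peaks, the split of gut genes and the tests with single gut lists or with the secretory list added, and the contrast at promoters that were not CpG-rich, were chosen after the data had been seen; the tests of the regulators of other organs and of gut genes were otherwise written before their values.

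Families of at least 15 genes sharing a symbol stem, chosen after their values were seen, extended the picture to 141 groups. Of these 16 were marked more often than other genes and 16 less often (two-sided Fisher exact tests, Benjamini-Hochberg adjusted). For the families marked less often, the mean in lists matched on CpG ran from 0.495 genes (Scgb) to 75.0 (Zfp). Where that mean is near 0, a low count says little beyond promoter CpG. Synaptotagmins, the calcium sensors of vesicle release, were marked in 13 of 17 cases and in 13 in each replicate (5.23-fold, exact p = 1.89e-08, adjusted p = 5.32e-07). Collagen genes were marked in 20 of 45 cases, 21 in replicate 1 and 19 in replicate 2 (3.04-fold, exact p = 1.54e-06, adjusted p = 3.58e-05). The inward rectifier potassium channels of the Kcnj family were marked in 8 of 15 cases, 11 in replicate 1 and 8 in replicate 2 (3.64-fold, exact p = 0.000518, adjusted p = 0.00521). Semaphorins, which guide axons, were marked in 9 of 20 cases, 10 in replicate 1 and 6 in replicate 2 (3.07-fold, exact p = 0.00112, adjusted p = 0.0083). The highest counts in lists matched on CpG were 11 for synaptotagmins, 17 for collagens, 8 for Kcnj and 12 for semaphorins. The Kcnj count thus only equalled the highest, and the semaphorin count lay within the matched range.

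Vomeronasal receptor genes, which sense pheromones, were marked in 0 of 331 cases, as in each replicate alone (exact p = 1.79e-23, adjusted p = 1.26e-21); lists matched on CpG had a mean of 5.26 marked genes. Zinc finger genes of the Zfp family were marked in 21 of 394 cases, 25 in replicate 1 and 15 in replicate 2 (0.359-fold, exact p = 5.74e-09, adjusted p = 2.02e-07), against a mean of 75.0 for lists matched on CpG. Histone genes were marked in 0 of 67 cases (exact p = 3.8e-05, adjusted p = 0.000487) and mitochondrial ribosomal protein genes of the Mrpl family in 0 of 49 (exact p = 0.000799, adjusted p = 0.00662), both at 0 in each replicate. With 1 gene per 100 kb, 3 of the 67 histone genes were left, against 8762 of all 21755 genes, so the histone genes lie close together and are not independent.

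The strongest pooled peaks by the authors' p, also chosen after their values were seen, were a pair on chromosome 17 (39843014 to 39846796 and 39847864 to 39848919). They overlapped no protein-coding gene but CT010467.1, annotated as a ribosomal RNA gene, and the non-coding genes Gm26917, Gm42418 and AY036118. Ribosomal RNA genes are repeated in the genome and no list of regions to exclude was used here, so these values are not read as a strong mark. Their −log10 p was 79.7 and 71.9, and their fold 2.36 and 2.27, both below the list's median of 3.10. The next was a peak over Otp, a hypothalamic regulator, with a −log10 p of 61.0 and a fold of 13.5.

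The frequent mark at regulators of other organs may reflect silencing of developmental regulators, a hypothesis found and tested on the same data. CpG-rich promoters alone were argued against, since 102 of the 111 were marked and the highest of 10000 matched lists reached 34. Neighbouring genes in shared domains were argued against by the excess with 1 gene per 100 kb (94.3% of 70 regulators against 18.1%, Fisher exact p = 1.32e-43). A single replicate did not account for it, since the larger p of the replicates alone was 4.94e-69. How far it was specific to other organs stayed open: 11 of 12 secretory and enteroendocrine regulators of the intestine were marked, and the contrast with epithelial regulators was 64 of 65 against 11 of 12 among CpG-rich promoters (exact p = 0.289) but 38 of 46 against 2 of 11 among the others (exact p = 0.000107); expression, and so silencing itself, was not analysed here.

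The 55 marked genes of the epithelial regulator, epithelial effector, mesenchyme, neural crest, and endothelial and blood lists had a cover of 70.6% ± 27.8 (SD over genes), and the 102 marked regulators of other organs 95.9% ± 9.44 (two-sided permutation p = 1e-05, the smallest these permutations can give). The lists were not alike: the mean was 54.6% ± 27.6 for 8 effectors and 55.0% ± 30.6 for 13 mesenchyme genes (permutation p = 1e-05 each), 80.8% ± 25.6 for 11 neural crest genes (median 97.6%, permutation p = 0.0016), 86.7% ± 14.7 for 10 endothelial and blood genes (median 90.9%, permutation p = 0.013) and 88.0% ± 22.2 for 11 secretory and enteroendocrine regulators (median 98.7%, permutation p = 0.031), which were not among the 55 and brought the gut mean to 73.5% ± 27.6 (permutation p = 1e-05). Among CpG-rich promoters the difference stayed (76.8% against 97.7%, permutation p = 1e-05), so CpG-poor promoters alone were argued against. The sets were not matched on the CpG ratio there, so CpG content may still contribute. A single replicate was argued against by the same permutation p in each, over the genes marked in that replicate and not the same 55 and 102. The cover was 60.6% for 66 gut genes against 93.4% for 104 regulators in replicate 1. In replicate 2 it was 54.7% for 54 against 86.4% for 102 (permutation p = 1e-05 each). Genes other than regulators in the gut lists were argued against by the 13 epithelial regulators alone, at 74.8% ± 25.1 (permutation p = 1e-05). A candidate explanation is a mark carried by only part of the cells of a mixed tissue, since the authors' fold was also lower, 6.68 ± 1.94 against 9.71 ± 1.73 in replicate 1 and 5.43 ± 1.71 against 7.38 ± 1.51 in replicate 2 (permutation p = 1e-05), but fold and cover are not independent and a weaker mark in every cell would give the same.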
